A study of Streptomyces coelicolor A3(2) with 11 samples.

How the data were processed

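Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on 11 strains of Streptomyces coelicolor A3(2) M145, a mycelial soil bacterium with a linear chromosome. Each strain carried 1 transcription regulator with a FLAG epitope tag, encoded on a plasmid integrated into a wild-type background, so that the regulator's own gene was present beside its tagged copy. The tag was at the C-terminus of 10 regulators and at the N-terminus of SCO3696. Per the labels' protocols, cultures of 25 ml in NMMP medium were grown for 46 h, fixed for 10 min in 1% formaldehyde at a temperature of 30 °C, sheared to fragments of 100 to 500 bp and precipitated with anti-FLAG beads, and part of the lysate was kept as input. Input and untagged-strain files were not used here. There was 1 library per regulator, so no spread between replicates can be given, and all tests below concern the positions within these libraries.

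Per the submitters' processing notes, the tools were Bowtie2 2.4.2, an aligner, and MACS3 3.0.3, a peak caller. The settings, and whether the input served as the control of the caller, are not given in the sources used here. The deposited files list, for each library, the peak intervals and 1 or more summits in each interval, called per library and not on pooled samples. The fold in the deposited files is the caller's ratio of the ChIP pileup to the background pileup at the summit, and it is the authors' value throughout. The deposited −log10 p and −log10 q are the caller's, and the deposited score is derived from them and served no purpose here. The lowest −log10 q was 20.1, so each list had already been restricted to strong evidence. Fold served to describe, rank and filter summits within a list, and folds of different libraries were not read as relative affinities. They were set side by side to describe the range of the series, at sites shared by SCO1262 and SCO5231 (by rank correlation and in a test of carry-over between these libraries), and in a test of rRNA operon summits against the weakest listed folds.

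Depth was recovered from the lists. The fold and the p of a summit together fix its ChIP and background pileups if fold is a ratio with a pseudocount of 1 and p is a Poisson tail, and under that reading the ChIP pileup came out whole, within 0.01, at 1175 of 1175 summits with a −log10 p under 1000. The Poisson tail was computed as a function continuous in the pileup, so that the solution was free to take fractional values. The median background pileup ran from 175 to 344 reads per library. Fold intervals are exact Poisson intervals (95%) of the ChIP pileup at a fixed background. They cover counting error only, leave out culture and precipitation error, and take the summit as given although it is the highest point of its peak. Intervals of shares are exact Clopper-Pearson intervals (95%), and neighbouring summits are not independent, so those intervals and the binomial tests are too narrow where summits cluster.

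The files name the chromosome AL645882 without a version. Gene names and neighbours came from a RefSeq gene table of assembly ASM20383v1, which had 7863 genes, 7619 of them with an older SCO locus tag. It gave neither strand, product names nor sequence. Whether the table fits the files' coordinates was checked from the data. Of the 1290 summits, 38.1% fell between genes with the table as given, and 10.2% fell between genes with the table moved by 500 bp either way, against 11.0% of the chromosome. Positions in the text are 1-based summit positions of the files. Names such as cydA or nagE2 that the table does not give are common usage for those locus tags and serve as background.

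The plan fixed before the data were examined called for promoter windows by strand. Because strand was not used here, windows were drawn at every gap of at least 50 bp between genes, from 300 bp outside to 100 bp inside each gene end that bordered the gap. These gap windows cover 21.5% of the chromosome, and a summit in a window was assigned to the bordering gene or genes, whichever their direction. A gene so assigned is called a target below, in the sense of position only. Gene list tests used as background the 6632 genes that border such a gap, since no other gene could be a target. The plan had named all annotated genes as background, and that choice was run as an alternative. Sequence analyses in the plan (known binding sites and recurring words under summits) were not run, nor were 4 gene lists defined by product words (sigma factors, transcriptional regulators, transporters and glycoside hydrolases). The list of ribosomal proteins was taken by gene symbol.

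Shares in gap windows and in the chromosome core (1.5 to 6.4 Mb, 56.5% of the chromosome) were tested by 2-sided exact binomial tests in the 10 libraries with at least 10 summits. Summits of different libraries were called shared within 150 bp, and were compared with 10000 random placements that kept each summit's class (in or outside gap windows), by a 1-sided test, for each of 55 pairs. The smallest p this test can give is 0.0001. Placements move each summit alone and so break up clusters of summits, which the circular shifts named below keep. Regions were built by linking summits within 150 bp, and regions with 4 or more regulators were counted against the same placements. Gene lists were tested by 2-sided Fisher's exact tests in libraries with at least 10 targets, 130 tests over 13 lists. These tests count genes that share a summit or an operon as separate, so p is too small where members do. The lists were GlcNAc and PTS, chitinases, heat shock and Clp proteases, the Rex regulon and respiration, development, the actinorhodin, undecylprodigiosin, calcium-dependent antibiotic and coelimycin clusters, other specialised metabolite clusters, pleiotropic regulators, ribosomal proteins, and tRNA and rRNA genes. Differences of median fold between classes of summits were tested by 2-sided permutation tests (100000 permutations) where each class had at least 5 summits. Adjusted p-values are Benjamini-Hochberg values within each family of tests, and the threshold was 0.05.

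Genes were named by a rule fixed before the data were examined. It takes the 5 summits of highest fold per library, the regulator's own gene, each bound member of the lists known for SCO5231, SCO3668 and SCO3320, up to 4 members of any other list per library, and the 5 regions bound by the most regulators. Genes named outside it are said to be so. Summits in rRNA operons are those within 300 bp of 1 of the 6 operons, a class set up after the data were seen. Alternatives were the 50% of summits with the highest fold in each list, a −log10 q of at least 10, a fold of at least 3, windows of 150 and 50 bp or 500 and 100 bp, the interval midpoint, other definitions of the core and of sharing, circular shifts of the lists, lists without regions of 4 or more regulators, and 3 or more regulators per region. Added after seeing the data were lists without rRNA operon summits, with 1 summit per interval, without each library in turn, and windows at gaps of any length.

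Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. The procedures were tested on simulated data. Planted pileups were recovered within 0.01 in 494 of 500 cases. For the location test, counts among 100 summits were drawn independently at the tested share, without positions or clusters. It called 9 of 200 such counts, and 200 of 200 drawn at a doubled share. How this test behaves with clustered summits was therefore not simulated. The pair test called 2 of 100 random pairs and 100 of 100 pairs with 10 planted shared summits. The list test called 4 of 200 random target lists and 200 of 200 with 5 planted members. The 8 planted regions of the simulated lists were all found.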

Results

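The binding of 11 FLAG-tagged regulators was mapped across the Streptomyces coelicolor chromosome at 46 h of growth, with 1 library per regulator and no replicates. The libraries list 1290 summits in 1035 intervals, from 2 summits for SCO3699 to 349 for SCO1186. SCO1145 had 283 summits, SCO1262 268, SCO2243 114, SCO5231 113, SCO3632 57, SCO3320 55, SCO3696 26, SCO4158 13 and SCO3668 10. Most summits were weak, and 358 of them (27.8%) reached a fold of 3 and 105 (8.14%) a fold of 10. The highest fold of a library ranged from 12.1 in SCO3668 to 1131 in SCO2243. Median background pileups of 175 to 344 reads set the counting error, so that a fold of 1.87 at the weak SCO3668 summit beside its own gene had an interval of 1.72 to 2.03.

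**Figure D1:**
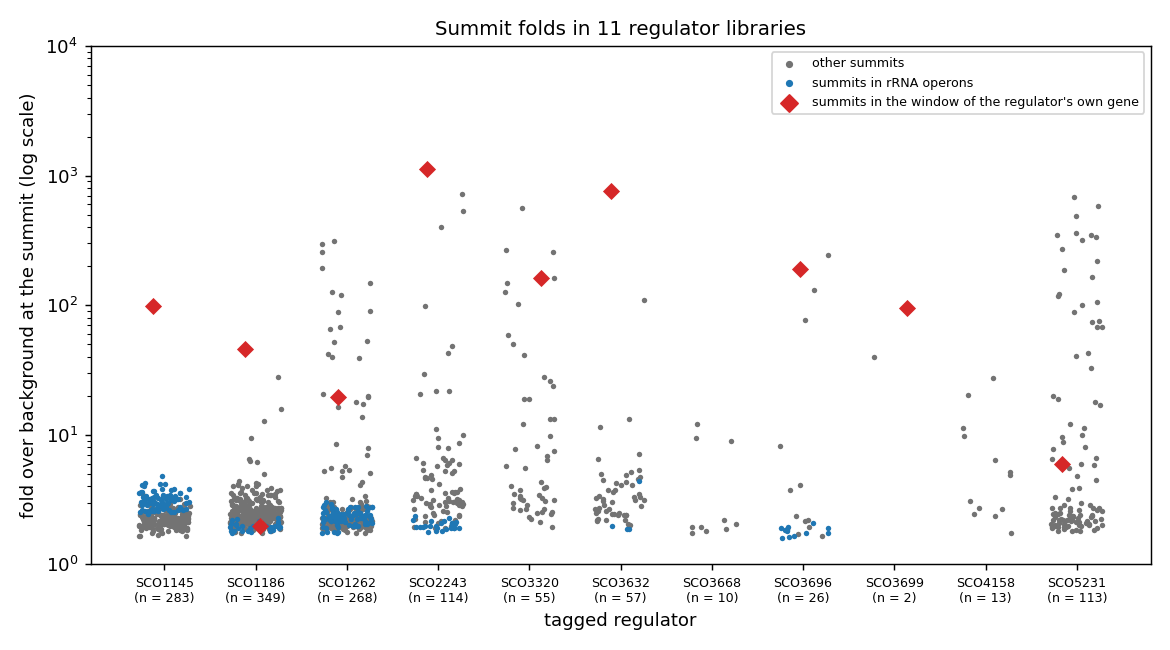
Fold over background (log axis) of each summit in the 11 libraries, with n summits per library on the horizontal axis; red diamonds mark summits in the window of the regulator's own gene and blue points those in rRNA operons. A summit in the own-gene window is the highest in 5 libraries, and rRNA operon summits do not exceed a fold of 4.79.

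The first question was which genes each regulator sits beside, starting with SCO5231, known as DasR, a GntR-family regulator of amino sugar uptake. Its highest summit lay between its own gene and dasA, which encodes a chitobiose-binding protein, at 684-fold (interval 681 to 687, position 5692181). SCO5841 (ptsH, a phosphotransferase system protein) followed at 579-fold, SCO1390 (crr, a further phosphotransferase component) stood at 349-fold, and SCO2907 (nagE2, the N-acetylglucosamine permease) shared a gap with SCO2906 at 349-fold. SCO2905 had a summit at 188-fold, SCO4285 at 219-fold and nagB, glucosamine-6-phosphate deaminase, at 76.0-fold. In all, 9 of 15 GlcNAc and PTS genes that border a gap were targets, against 0.256 expected (adjusted p = 1.05e-11, Fisher's exact test). All 9 of 9 chitinase genes were targets too (exact test, adjusted p = 1.14e-14), from SCO1444 at 363-fold, SCO5376 at 338-fold and SCO2503 at 272-fold through SCO6012 at 122-fold, SCO1429 at 117-fold, SCO5003 at 68.1-fold and SCO7263 at 32.7-fold to SCO5673 at 11.2-fold and SCO5954 at 8.82-fold. The remaining summit among the top 5 lay between SCO7224 and SCO7225 at 491-fold. A further summit at the end of the SCO5231 gene stood at 5.91-fold.

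SCO1262 sat beside the same chitinase genes. It had 9 of 9 chitinases (Fisher's exact test, adjusted p = 2.02e-13) and 5 of 15 GlcNAc and PTS genes (adjusted p = 4.21e-04) among its targets. Its top summits lay beside SCO6032 (312-fold), between SCO2833 and SCO2834 (297-fold), between SCO5376 and SCO5377 (258-fold), between SCO7224 and SCO7225 (192-fold) and between SCO5953 and SCO5954 (149-fold). SCO5003 followed at 126-fold and SCO6012 at 119-fold. Its summit at dasA reached 68.4-fold, at SCO1390 6.96-fold, at SCO5231 5.26-fold and at SCO5841 5.08-fold. SCO1262 and SCO5231 shared 49 of the 113 SCO5231 summits, against 1.42 in random placements (permutation p = 0.0001, the smallest possible, adjusted p = 0.000289), with a median distance of 12 bp. Of the 31 SCO5231 summits of at least 10-fold, 25 had a SCO1262 summit, and of the 24 such SCO1262 summits, 21 had a SCO5231 summit. Across the 49 shared sites, which are not independent replicates, the folds of both libraries were correlated (Spearman rho = 0.78, permutation p = 1e-05, the smallest possible). In a check added after the data were seen, rho was 0.17 among the 25 shared sites of at least 10-fold in SCO5231 (permutation p = 0.418, adjusted p = 0.418) and 0.63 among the 24 weaker ones (p = 0.00128, adjusted p = 0.00256).

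**Figure D2:**
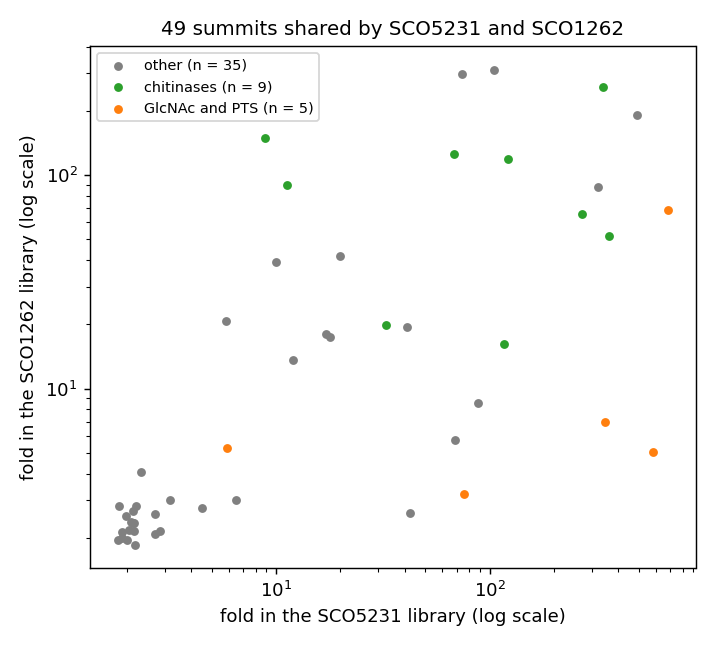
Fold in the SCO1262 library against fold in the SCO5231 library (both axes log) at the 49 shared summits, one point per SCO5231 summit, with chitinase genes in green (9 summits) and GlcNAc and PTS genes in orange (5 summits). SCO5841, ranked 2 in the SCO5231 list at 579-fold, is ranked 33 in the SCO1262 list at 5.08-fold.

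SCO3320, known as Rex, a redox-sensing repressor of respiratory genes, had its highest summit beside SCO3945 (cydA, cytochrome bd oxidase) at 557-fold (interval 554 to 560, position 4340835). Summits between SCO6168 and SCO6169 (264-fold), between SCO5240 and SCO5241 (255-fold), beside SCO3093 (163-fold) and at its own gene (161-fold) completed the top 5. SCO4562 (nuoA, the start of the NADH dehydrogenase operon) had 126-fold and SCO5366, the start of the ATP synthase operon, 50.1-fold. Of 21 genes of the Rex and respiration list that border a gap, 4 were targets against 0.222 expected (Fisher's exact test, adjusted p = 0.000967).

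SCO3668, known as HspR, the repressor of the dnaK operon, had 3 strong summits, and each lay beside a chaperone or protease gene. They were dnaK at 12.1-fold (interval 11.7 to 12.5), clpB at 9.39-fold and lon at 8.98-fold. These are 3 of 14 heat shock and Clp protease genes (Fisher's exact test, adjusted p = 2.65e-05). The other 7 summits did not exceed 2.21-fold, with SCO2529 at 2.21 and the gap between SCO5244 and SCO5245 at 2.04. With a fold of at least 3 or the 50% of summits with the highest fold, too few targets were left for the list test.

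SCO2243 had the strongest summit of the series, between SCO2242 and its own gene, at 1131-fold (interval 1126 to 1136, position 2412308). Its next summits lay between rmdB and SCO5496 (715-fold), between SCO6121 and SCO6122 (535-fold), beside SCO1750 (403-fold) and between SCO6966 and SCO6967 (99.2-fold). Among its targets 6 of 78 tRNA and rRNA genes were found (Fisher's exact test, adjusted p = 0.00160), a call that was lost without summits in rRNA operons, among the 50% of summits with the highest fold (2 genes, adjusted p = 0.817) and at a fold of at least 3 (2 genes, adjusted p = 0.825). SCO3632 also peaked at its own gene, at 756-fold, followed by the gap between SCO0875 and SCO0876 (110-fold), SCO4699 (13.3-fold, inside the gene), SCO5125 (11.5-fold, inside the gene) and the gap between SCO2248 and SCO2249 (7.15-fold). lexA, the repressor of the DNA damage response, had a SCO3632 summit at 5.30-fold.

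SCO3696 and SCO3699, whose genes lie close together, each had a strong summit at the own gene, and they shared no summit. SCO3696 had 245-fold beside SCO6828, 190-fold at its own gene, 130-fold between SCO6829 and SCO6830, 76.4-fold between SCO6811 and SCO6812 and 8.21-fold beside SCO6831. The only summits of SCO3699 were its own gene at 95.7-fold (position 4079006) and the gap between SCO6835 and SCO6836 at 40.2-fold (position 7606733). SCO4158 bound the gap between SCO3919 and SCO3920 (27.3-fold), the inside of SCO7268 (20.1-fold), the gap between deoC (deoxyribose-phosphate aldolase) and SCO4915 (11.3-fold), the gap between SCO4885 and SCO4886 (9.87-fold) and that between SCO4900 and SCO4901 (6.39-fold).

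SCO1186, which lies beside the cellulase gene SCO1187 (celB), had its top summit in the gap between these genes at 46.1-fold (interval 45.2 to 47.1). Below it came the gaps between SCO0765 and SCO0766 (27.9-fold), beside SCO7637 (15.9-fold), between SCO0643 and SCO0644 (12.8-fold) and beside SCO6546 (9.36-fold). SCO1145 had a single strong summit, at its own gene (98.0-fold), and its second summit, inside the rRNA gene SCOr02, reached 4.79-fold, followed by SCOr05 (4.21), SCOr08 (4.18) and SCOr17 (4.16). Of 42 developmental genes that border a gap, 7 were SCO1145 targets (Fisher's exact test, adjusted p = 0.00160), all weakly bound, with SCO3926 (ssgA) at 3.18-fold, bldC at 2.79-fold, SCO3323 (bldN) at 2.66-fold and SCO3034 (whiB) at 2.39-fold. At a fold of at least 3 this call was lost (1 gene, exact adjusted p = 0.799). SCO1145 and SCO1262 had 19 and 18 of 78 tRNA and rRNA genes among their targets (exact tests, adjusted p = 4.37e-12 and 1.05e-11), and these calls were lost without rRNA operon summits, for SCO1145 also with 1 summit per interval, and for SCO1262 also at a fold of at least 3. All 18 in SCO1262, and all in SCO1145 but SCOt28, were rRNA genes of the 6 operons. Genes of 1 operon, and genes assigned the same summit, are not independent, so these p-values are too small. The other 7 lists (the actinorhodin, undecylprodigiosin, calcium-dependent antibiotic and coelimycin clusters, other specialised metabolite clusters, pleiotropic regulators and ribosomal proteins) gave no call in any tested library, and the lowest adjusted p was 0.220, for 2 coelimycin genes, SCO6279 and SCO6280, in the SCO3320 library.

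Whether the regulators bound beside their own genes was asked next. A summit lay in the window of the own gene in 9 of 11 libraries and was the strongest of the list in 5 (SCO1145, SCO1186, SCO2243, SCO3632 and SCO3699). It ranked 2 in SCO3696, 5 in SCO3320 and 19 in SCO1262 (19.6-fold). In SCO5231 the summit in the window ranked 39 and lay inside the gene, while the highest summit of the list, in the gap shared with dasA, lay 345 bp from the gene and so outside its window. These 2 summits belong to the same called interval. SCO3668 and SCO4158 had no summit in the window, but SCO3668 had 1 at 1.87-fold in the gap of 5 bp between its gene and dnaJ, too short for a window, and SCO4158 had 2 inside its gene. The highest SCO3668 summit, beside dnaK (12.1-fold), lies farther along the same run of genes. Whether dnaK and SCO3668 are transcribed together was not examined, so binding at a joint promoter is not counted here. Counting any gap beside the own gene, whatever its length and the distance, 10 of 11 libraries had a summit there, a count made after the data were seen. Within 10 kb of the own gene lay 22 summits over all libraries, 5 of them of SCO1186, and 3 of 10 for SCO3668 (30%, interval 6.67% to 65.2%), whose dnaK and clpB summits are close to its gene. Between regulators, 2 links were found in gap windows. SCO3632 had a summit beside SCO3668 at 4.44-fold, ranked 13 of 57, at the end of that gene away from dnaJ. SCO1262 had one at 5.26-fold, ranked 31 of 268, inside SCO5231 at its end near SCO5230. SCO1262 also had a far stronger summit (68.4-fold, ranked 10) in the gap between SCO5231 and dasA, too far from SCO5231 for its window. With windows of 500 and 100 bp this SCO1262 summit counted too, which gave 3 summits for the same 2 pairs of regulators.

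Summits lay in gap windows more often than the 21.5% of the chromosome that these cover in 9 of 10 libraries tested. The share was 76.9% for SCO4158, 71.9% for SCO3632 (interval 58.5% to 83.0%), 70% for SCO3668, 69.1% for SCO3320 and 61.1% for SCO5231 (51.4% to 70.1%, exact binomial test, adjusted p = 1.17e-18). It was lower for SCO1145 (44.5%), SCO1262 (41.8%), SCO1186 (41.5%) and SCO2243 (33.3%, exact adjusted p = 0.00447). SCO3696 at 38.5% (20.2% to 59.4%) missed the threshold of the exact test (adjusted p = 0.0519), and passed it at 71.4% without rRNA operon summits. At a fold of at least 3, SCO1145 stood at 20.8%, but 49 of these 53 summits lay in rRNA operons. Of the other 4, 3 lay in gap windows, too few for the test. With summits of any fold, its share without rRNA operon summits was 53.1% (exact adjusted p = 8.64e-21). Fold was higher in gap windows than elsewhere in 2 of 8 libraries tested, SCO3696 (median 6.15 against 1.81, permutation adjusted p = 0.00128) and SCO5231 (6.66 against 2.23, adjusted p = 0.00204).

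The core of the chromosome, 56.5% of its length, held more than its share of summits in 8 of 10 libraries. The shares were 92.3% for SCO4158, 83.6% for SCO3320, 82.0% for SCO1145 (interval 77.0% to 86.3%), 80.2% for SCO1186, 77.2% for SCO3632, 76.1% for SCO5231, 72.0% for SCO1262 and 67.5% for SCO2243 (exact binomial test, adjusted p = 0.0226). SCO3668 (90%, adjusted p = 0.0563) and SCO3696 (73.1%, adjusted p = 0.113) missed the threshold of the exact test. The excess was lost for SCO1262, SCO2243, SCO3632 and SCO5231 among summits of at least 3-fold and among the 50% with the highest fold. The implied background pileup fell with distance from the replication origin, which lies in the core, in 8 of 10 libraries by a permutation test chosen after the data were seen, and SCO3668 and SCO3696 missed its threshold. In SCO1186, SCO1262, SCO2243, SCO3320, SCO3632, SCO3696 and SCO5231 its median beyond 3 Mb was about the lowest value of the library. In SCO4158, with 1 summit beyond 3 Mb, it was so too.

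Sharing of sites between regulators was widespread among weak summits. Of 55 pairs, 23 shared more summits than random placements. SCO1145 and SCO1262 shared 148 of the 268 SCO1262 summits (3.17 by chance), SCO1145 and SCO1186 shared 104 (4.24 by chance), and SCO1186 and SCO5231 shared 63 (1.96 by chance), each with a permutation p = 0.0001, the smallest possible, and adjusted p = 0.000289. SCO1145 and SCO1262 each had 91 summits in the near-identical rRNA operons, so part of their sharing can be the same sequence counted once per copy. Without rRNA operon summits 21 pairs passed, and with circular shifts 25. SCO3320, SCO3699 and SCO4158 were in none of the 23 pairs. All pairs among SCO1145, SCO1186, SCO1262, SCO3668, SCO3696 and SCO5231 passed, and none among SCO2243, SCO3320, SCO3632, SCO3699 and SCO4158. These sets are also the later and the earlier block of the sample order. The remaining calls were SCO2243 with each of the first set, and SCO3632 with SCO1145 and SCO1262. No batch is known and no untagged strain was used here, so joint handling cannot be told apart from common binding. Only SCO1262 with SCO5231 passed among summits of at least 3-fold, 9 pairs passed among the 50% of summits with the highest fold, and 10 pairs passed without regions of 4 or more regulators. Fold was lower at shared than at unshared summits in SCO2243 (median 2.10 against 3.98, permutation adjusted p = 0.000320) and SCO3696 (1.83 against 76.4, adjusted p = 0.00140), and slightly higher in SCO1262 (2.35 against 2.19, adjusted p = 0.0190), among 8 libraries tested. With any overlap of intervals as sharing, the SCO1262 call was lost (permutation adjusted p = 0.908) and SCO1145 gained one (higher by 0.325 at shared summits, adjusted p = 0.00800).

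**Figure D3:**
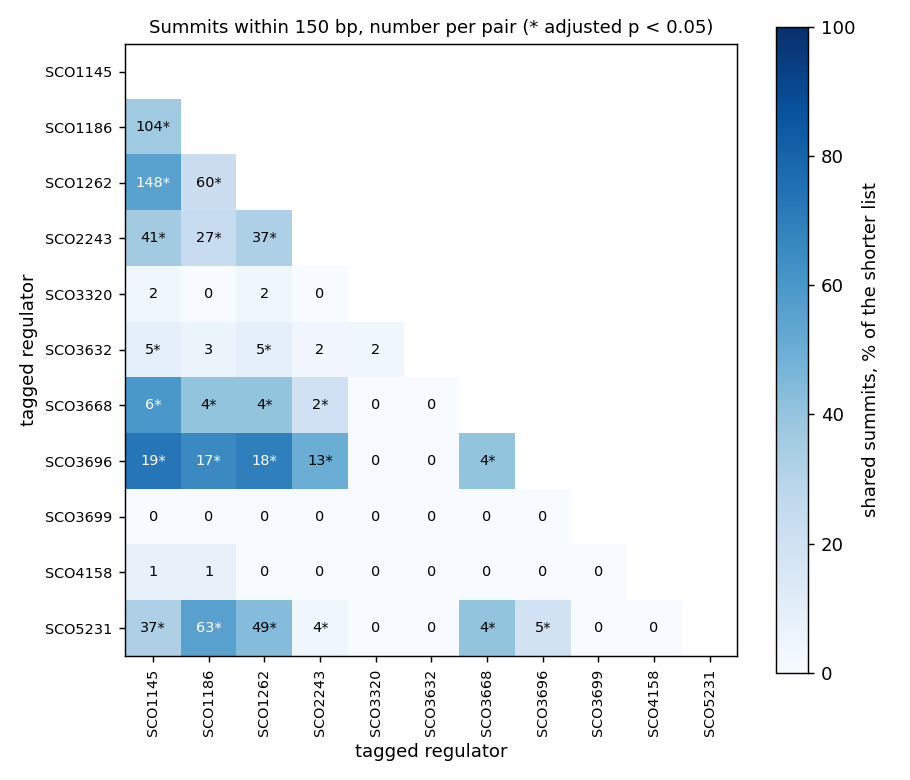
Number of summits of the shorter list within 150 bp of a summit of the other list for each of the 55 pairs, shaded by percent of the shorter list; asterisks mark the 23 pairs with an adjusted p below 0.05. SCO1145 and SCO1262 share 148 summits, and SCO3320, SCO3699 and SCO4158 have no marked pair.

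Regions with 4 or more regulators numbered 38, against 0.0119 in random placements (permutation p = 0.0001, the smallest possible). All 38 included SCO1145, SCO1186 and SCO1262, 26 included SCO2243, and 15 each included SCO3696 and SCO5231. The regions with the most regulators lay inside SCO3621 (7 libraries, position 4000193), inside SCO6921 (7 libraries, position 7684455), in the gap between cobC (SCO1859) and SCO1860 (6 libraries), and, of 15 regions tied at 5 libraries, by rank sum, inside the rRNA gene SCOr11 and inside SCO3379. Of the 38 regions, 19 lay in rRNA operons, and no summit in any of them exceeded 4.79-fold. There were 1 region among summits of at least 3-fold, 3 among the 50% of summits with the highest fold, 21 with 1 summit per interval, and 18 each without the SCO1145, the SCO1186 or the SCO1262 library.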

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

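The test here was chosen only after the data were seen. The background pileup implied by the fold and p of each summit served for the fold intervals. Its course along the chromosome is mentioned in the report only beside the core shares. The background fell with distance from the gap between dnaA and dnaN, where replication starts, with a median Spearman rho of -0.65 over 10 libraries (from -0.90 in SCO3320 to -0.37 in SCO3696, across summits, which are not independent replicates). The permutation adjusted p was below the threshold in 8 of 10 libraries, and SCO3668 (0.234) and SCO3696 (0.0729) missed it. The median background within 1 Mb of the origin was 1.43 times that beyond 3 Mb in SCO1262 and 1.26 times in SCO5231. It was 0.900 times in SCO3668, which has 1 summit beyond 3 Mb. Beyond 3 Mb the median was 149 in SCO1262 and 180 in SCO5231, and so was the lowest background of each library. The same held in SCO1186 (180), SCO2243 (148), SCO3320 (202), SCO3632 (290) and SCO3696 (215). It also held in SCO4158 (282), with 1 summit beyond 3 Mb, but not in SCO1145 (234, lowest value 215) and SCO3668. The implied background thus appears cut off from below in the libraries where it held. The ratios and rho there describe that cut-off value and not local depth alone.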

How the results depend on the processing

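Of 246 alternative values with a test, 220 kept their side of the threshold. A further 6 reversed, that is, changed direction with the reported or the alternative value passing. The 220 include values that changed direction without passing in either setting. The core share of SCO3696, for example, went from 73.1% to 46.2% with the 50% of summits of highest fold, against 56.5% of the chromosome. Of 54 counts, 43 stayed within 1.5 times the reported one. These numbers leave out the alternative of a −log10 q of at least 10, which removed no summit and is void. The sequence searches and their alternatives were not run. With the 50% of summits with the highest fold, and with a fold of at least 3, the shorter lists were too short for some tests, which then give no value. The heat shock list of SCO3668 has none there, with windows of 150 and 50 bp or without regions of 4 or more regulators. Causes were not tested, except where removing the summits in question is the alternative itself. With the 50% of summits of highest fold, the gap-window share of SCO3696 passed at 69.2%, the core shares of SCO1262 (61.2%), SCO2243 (59.6%), SCO3632 (65.5%) and SCO5231 (68.4%) no longer passed, 9 pairs passed in place of 23, and 3 regions of 4 or more regulators stood in place of 38. With a fold of at least 3, the gap-window share of SCO1145 turned to 20.8%, just under the 21.5% of the chromosome, with 49 of its 53 summits in rRNA operons (53.1% without rRNA operon summits at any fold), the core share of SCO1262 turned to 47.7%, those of SCO2243 (61.7%), SCO3632 (67.7%) and SCO5231 (63.8%) no longer passed, 1 pair and 1 region were left, and SCO1262 had 0 tRNA and rRNA genes. With the middle 50% of the chromosome as core, SCO2243 (57.0%) no longer passed. With 3 or more regulators there were 93 regions. Without regions of 4 or more regulators, 10 pairs passed. The following alternatives, up to those without a library, were chosen after seeing the data. Without rRNA operon summits, the gap-window share of SCO3696 passed at 71.4%, the core share of SCO2243 (60.9%) did not pass, 19 regions were left, and the tRNA and rRNA genes numbered 1 in SCO1145 and 0 in SCO1262. With 1 summit per interval, the gap-window share of SCO3696 passed at 41.7%, the core share of SCO2243 (66.0%) did not pass, 21 regions were left and SCO1145 had 1 tRNA or rRNA gene. Without the SCO1145, the SCO1186 or the SCO1262 library, 18 regions were left each time, and without any other library 28 to 38. Pairs numbered 16 to 24 with each library left out in turn. Over all settings, the other 7 changed values were the SCO2243 tRNA and rRNA call, lost with the 50% of summits of highest fold, at a fold of at least 3 and without rRNA operon summits, the SCO1145 development call, lost at a fold of at least 3, and 3 fold comparisons. Of these, SCO1262 gained a difference between gap windows and elsewhere (0.353, permutation adjusted p = 4.5e-05) with windows of 150 and 50 bp, and with any overlap of intervals SCO1145 gained and SCO1262 lost a difference at shared summits. A call of tRNA and rRNA genes in SCO5231 was gained with the 50% of summits of highest fold (5 of 78, exact adjusted p = 0.0385), at a fold of at least 3 (0.0300) and with windows of 500 and 100 bp (6 of 78, 0.0466). The 10 list calls were the same 10 with all annotated genes as background. Counting depth limits the weak summits most, and the lack of replicates limits all of them.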

Other observations

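The tests in this part were chosen only after the data were seen. Beyond the genes named by the rule, SCO5231 had a summit at 164-fold between the tRNA genes SCOt58 and SCOt59 and at 99.6-fold beside SCO5238, neither with a SCO1262 summit, and SCO1262 had 52.7-fold beside SCO7069 and 40.1-fold between SCO0914 and SCO0915 without a SCO5231 summit. SCO4158 had a summit beside purS, a purine synthesis gene, at 5.14-fold. Of the regions with 4 or more regulators, 4 lay inside SCO6273, SCO6274 and SCO6275, the polyketide synthase genes of the coelimycin cluster. These items were chosen after their values were seen.

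The strong SCO1262 summits coincide with SCO5231 summits, and carry-over of DNA between the libraries is a technical explanation. If the SCO5231 library had leaked into the SCO1262 library at the lowest ratio of excess fold seen among shared strong sites, 4 strong SCO5231 summits would have exceeded the weakest listed SCO1262 fold of 1.74 and yet have no SCO1262 summit (nagE2 would stand at 3.46-fold). In the other direction 3 strong SCO1262 summits argue against it in the same way. Neither leak can then be the whole cause, while a smaller one stays open. Whether both proteins read the same DNA sequence was not tested here.

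Weak summits in the rRNA operons appeared in 6 libraries, among them 91 each in SCO1145 and SCO1262. A uniform capture of these operons in every library is argued against by 3 libraries (SCO3668, SCO4158 and SCO5231) that list summits weaker than the lowest median rRNA fold of 1.81 and none in an rRNA operon. Reads shared between near-identical operon copies cannot be told apart from equal binding, since the highest folds of the 6 operons in SCO1145 differed by 1.20 times (4.00 to 4.79), as either would give, and no sequence was used. No biological explanation was tested.

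A summit inside the regulator's own gene was listed 5 times in 4 libraries, and the technical explanation weighed is a single second copy of the tagged gene on the integrated plasmid as the whole cause. It would give at most about 2-fold, and less if the caller's background came from the same strain, which is not known here. The interval lay above 2 for 3 of them, narrowly in SCO1262 (2.28-fold, 2.05 to 2.53) and clearly in SCO4158 (2.66-fold, 2.50 to 2.84) and SCO5231 (5.91-fold, 5.58 to 6.26), which argues against it. The SCO5231 summit lies 28 bp from a SCO1262 summit of 5.26-fold, so that site is not confined to the library with the extra copy. It also lies in the same called interval as the 684-fold summit at dasA, so it is not a separate peak and weighs less here. SCO4158 also had a summit at 1.74-fold with an upper bound of 1.89, below 2, and SCO1186 one at 2.19-fold (1.98 to 2.42), so a part played by the copy, and binding inside these genes, stay open.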
